A study of Homo sapiens with 5 samples.

How the data were processed

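The starting values were raw counts: per the file headers, the deposited matrices hold a whole-number count of UMIs for each gene and cell barcode, written by Cell Ranger 6, and per the submitters' processing notes the authors aligned reads to hg38. No normalization had been applied to these counts, and the values in the files, whole numbers of 1 or more, were checked to be counts. The gene annotation and the rule by which the authors called cells are not given in the sources used here. The files list 36601 genes and 45911 barcodes in 5 libraries, and 34616 of the gene identifiers were found in GENCODE release 29, from which positions were taken. The sgRNA screen that the series description mentions was not analysed here.

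Barcodes with at least 500 detected genes and at most 25% of UMIs from mitochondrially encoded genes were kept, which left 44362 cells and between 289407369 and 345406971 UMIs per library. Counts were summed per library over the kept cells, since cells of 1 library are not replicates. CPM is the count scaled in the usual way by the total UMIs of the kept cells of a library. The comparisons, tests, gene lists, cell filters and alternatives were fixed before the data were examined, apart from those named below as added later.

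Sums were fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided), with TMM factors between 0.941 and 1.04, for 13944 genes at 1 CPM or more in at least 2 libraries, and p values were adjusted by the method of Benjamini and Hochberg over all genes tested. Treatment and line were the terms of 1 additive fit with 2 residual degrees of freedom, and their interaction was added in another fit with 1 residual degree of freedom, from the WT day 28 and day 42 libraries. The common dispersion of the additive fit, 1 value shared by all genes, was equal to a coefficient of variation between libraries of 11.6% beyond counting error. Lines and days therefore take the place of replicates. Each SE was worked back from the test, as the size of the log2 fold change over the square root of its F statistic. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, with a preset correlation between genes of 0.01 and with an estimated one, adjusted over the lists with enough members. With an estimated correlation camera works with the 2 or 1 residual degrees of freedom of the fit. No list passed that way in any comparison, not even mitosis, of which 29 of 29 members fell on differentiation. A call lost that way therefore does not argue against a list. DESeq2 1.42.0 was run as an alternative. WT day 42 and WT day 28 were compared by the log2 ratio of CPM with 1 CPM added, for genes at 20 CPM or more, with exact Poisson intervals, and the median of each list was placed among 10000 random lists matched on size and expression.

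The lists covered hepatocyte secreted proteins, phase I enzymes with cytochrome P450, phase II enzymes, transporters, bile acid synthesis, the urea cycle with amino acid catabolism, gluconeogenesis, fatty acid oxidation, cholesterol synthesis, lipogenesis, liver transcription factors, complement with coagulation, acute phase, cholangiocyte, fetal liver, DNA replication, mitosis, mesenchymal, endothelial, and macrophage and lymphocyte genes. They also covered the unfolded protein response, immediate early genes, p53, interferon, NF-kB, metallothioneins, glucocorticoid, NRF2, TGF-beta with YAP, Wnt, mitochondrial mRNAs, glycolysis and ribosomal proteins. The symbols G6PC1 and RIGI are not in the files, and GGT1 is shared by 2 gene identifiers and was not matched.

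Genes were named by rule. For each of the 2 main contrasts the rule took the 10 largest log2 fold changes in each direction among genes with an official symbol, an adjusted p under 0.05, a mean log2 CPM of 4 or more and the same sign in every matched pair of libraries. The interaction gave the 5 largest in each direction with an adjusted p under 0.05 and a mean log2 CPM of 4 or more, the WT day 42 comparison the 10 largest ratios in each direction, each list up to 4 members with the largest change, and ALB, CYP3A4, KRT19, KRT7, MKI67, HNF4A, VIM, AFP and SLC10A1 were always included. List members with 3 counts or fewer in a library group are not named with a fitted fold. Some genes that the rule picked are not reported here. PAGE5 was named outside the rule, after its values were seen, because so few genes passed.

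Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 in Python 3.11.15, on 30 principal components of 2000 variable genes, after scaling each cell to 10000 counts, with 15 neighbours and a resolution of 0.5. Clusters were named from the marker lists when at least 3 markers were 2-fold higher than in other cells at 20 CPM or more and at least 3 lay among the 50 leading genes. No other class could have more markers among the 10 leading genes. Clusters far shallower than their libraries stayed unnamed if no marker of the class lay among those 10. These conditions are the second of 2 naming rules: the first asked for 1 marker among the 10 leading genes, and the thresholds were changed after the clusters had been seen. In the main clustering both rules gave the clusters described the same names. Scrublet called 37 of 44362 cells as doublets, too few to be taken as an estimate, so leaving out the cells with the highest scores (507 of 7161 in WT day 5 to 894 of 11621 in dCas9 day 28) was added as an alternative after seeing the data, as was leaving out day 5 cells in clusters of mostly differentiated cells. Shares of cells with a UMI were computed after thinning each cell to 20000 UMIs, with exact Clopper-Pearson intervals, and cells under that depth were left out (358 in WT day 42 to 2048 in dCas9 day 28).

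The fits were tested on simulated data with the same libraries and depths, in which 50 genes were given each of the folds 1.5, 2, 4 and 8. The differentiation fit recovered 62%, 98%, 96% and 96% of them, with 8.81% of its calls false, and the line fit recovered 42%, 98%, 98% and 98%, with 4% false. The interaction fit recovered 4%, 66%, 96% and 98%, with 25% false.

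Alternatives were RLE size factors, DESeq2, no low-count filter, filterByExpr, all barcodes, cells of at least 1000 genes and at most 10% mitochondrial UMIs, called doublets left out, equal numbers of cells (7161 per library), thinned cells, each fit without the other factor or without day 42, and each library left out in turn. For single-library comparisons they were other pseudocounts, minima and scalings, and for clusters the resolution, thinning, clustering of the differentiated libraries alone and the naming rule. Genes of the sex chromosomes that mark sex were left out of the named genes.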

Results

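HepaRG is an established human liver progenitor cell line that divides in culture and takes on hepatocyte features when it is kept with dimethyl sulfoxide. RNA of single cells was counted as unique molecular identifiers (UMIs) by droplet sequencing (10x Genomics) in 5 libraries, after sorting for cells that excluded Sytox Green, a dye that enters dead cells. Wild-type cells (WT) and a line carrying dCas9-KRAB, a nuclease-dead Cas9 fused to a repressor domain (dCas9), were each captured while proliferating on day 5 and after differentiation on day 28. WT cells were also captured on day 42 of differentiation. Each line and day was 1 library, with no replicate of the same line and day. The dCas9 day 28 library carries Cas9 in its deposited name and dCas9-KRAB in its label, and was taken as labelled; its ZNF10 level, 86.6 CPM against 109 CPM in dCas9 day 5 and at most 5.38 CPM in WT, is that of a dCas9 library.

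The libraries held 7161 cells (WT day 5), 8649 cells (dCas9 day 5), 9495 cells (WT day 28), 11621 cells (dCas9 day 28) and 7436 cells (WT day 42) that passed the filters. Their total counts lay between 289407369 UMIs in WT day 42 and 345406971 UMIs in dCas9 day 28. The median UMIs per cell were 38445, 35908, 29203, 25807 and 33781, in the same order. The median share of UMIs from mitochondrially encoded genes was 6.32% and 6.31% in the WT and dCas9 day 5 libraries, and 10.6%, 13.9% and 13.02% in WT day 28, dCas9 day 28 and WT day 42. Expression is given in CPM, the usual scaling of counts by the total UMIs of the kept cells of a library, and intervals on the values of single libraries are exact 95% intervals that cover counting error only.

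The comparison of differentiated with proliferative libraries asked which genes distinguish HepaRG cells in their differentiated state. In whole libraries, genes of hepatocyte function were far higher after differentiation, and genes of cell division and of the extracellular matrix were far lower, in both lines. Not all differentiated cells shared the rises. In the 2 largest unnamed clusters of differentiated cells, ALB and HNF4A were lower than in the day 5 clusters, while CYP3A4 and TTR were higher, as given below. CYP3A4, the main drug-metabolising cytochrome P450 of adult liver, rose by 10.49 (log2 fold change, SE 0.32, edgeR adjusted p = 3.97e-07), from 0.135 and 0.299 CPM in the 2 proliferative libraries to 248, 281 and 330.0 CPM in the 3 differentiated libraries. ALB, which encodes serum albumin, rose by 4.10 (SE 0.25, edgeR adjusted p = 5.22e-06), from 336 and 511 CPM to 5442, 6769 and 7715 CPM. POSTN, which encodes the matrix protein periostin, fell by 8.40 (SE 0.25, edgeR adjusted p = 3.18e-07), from 579 and 334 CPM to 1.12, 1.13 and 1.85 CPM. MKI67, a marker of dividing cells, fell by 2.24 (SE 0.14, edgeR adjusted p = 6.89e-06), from 194 and 141 CPM to 32.3, 29.2 and 46.3 CPM.

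Among genes with a mean log2 CPM of 4 or more, the other genes with the largest rises were AGXT (9.78), a glyoxylate-detoxifying enzyme of the hepatocyte peroxisome, ACSM2A (9.77), ADH1B (9.14), the fatty acid binding protein gene FABP1 (8.92), the thyroxine carrier TTR (8.68), the sulfotransferase SULT2A1 (7.92), GPX2 (7.09), the iron carrier TF (6.65) and CPB2 (6.55). ADH1B has close paralogs, so reads of its family are uncertain in their assignment. Other genes with large falls were IGFL3 (-8.54), SCG5 (-7.00), S100A2 (-6.27), the smooth muscle gene TAGLN (-5.41), PPBP (-5.40), GLIPR1 (-4.93), the matrix proteoglycan LUM (-4.72) and PAPPA (-4.44). Each of these genes moved the same way in WT day 28 against WT day 5, WT day 42 against WT day 5 and dCas9 day 28 against dCas9 day 5. In the GENCODE annotation of hg38, CYP3A4 (ENSG00000160868) lies on chromosome 7 at 99756960 to 99784265 on the minus strand, and ALB (ENSG00000163631) lies on chromosome 4 at 73397114 to 73421412 on the plus strand. Both are protein-coding genes.

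**Figure D1:**
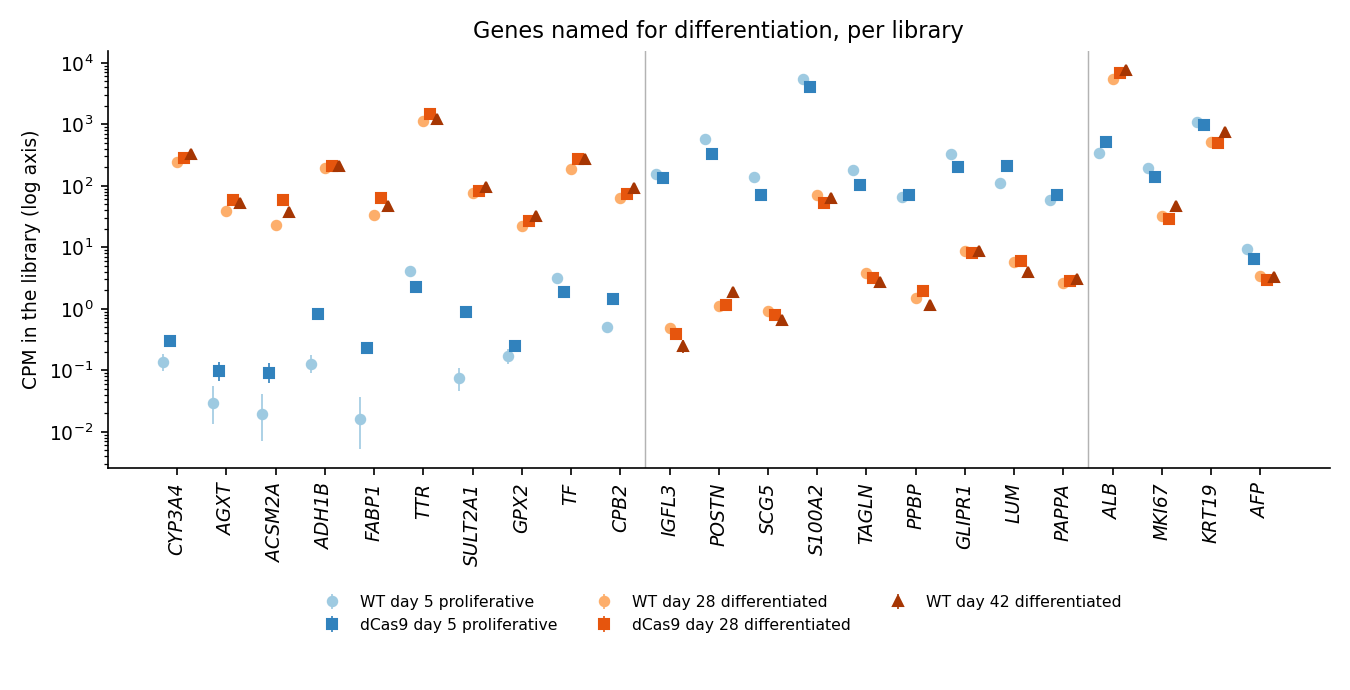
CPM in each of the 5 libraries, on a log axis, of the 10 genes with the largest rises among those with a mean log2 CPM of 4 or more, 9 genes with large falls, and ALB, MKI67, KRT19 and AFP; each point is 1 library and its bar is the 95% counting interval. The 3 differentiated libraries lie on one side of the 2 proliferative libraries for every gene shown, as for CYP3A4 with 248 CPM or more against 0.299 CPM or less.

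Genes that encode proteins secreted by hepatocytes rose as a group. All 18 tested members of the secreted protein list rose, including the apolipoproteins APOA2 (6.41) and APOC3 (6.39). Of 23 tested complement and coagulation genes, 21 rose and 1 fell, with plasminogen (PLG, 9.42) and kininogen (KNG1, 9.07) among the rises. Of 12 acute phase genes, 10 rose and 2 fell, and the rises included haptoglobin (HP, 4.54), FGL1 (4.21), SAA2 (3.65) and ITIH4 (3.46). SAA2 and SAA1 are near-identical, so their split is uncertain. By camera with a preset correlation these 3 lists had adjusted p values of 4.03e-09, 1.29e-06 and 0.00824. All 3 calls were lost otherwise, with adjusted p = 0.499 with an estimated correlation, a form of camera that called no list in any comparison.

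Genes of drug and bile acid handling also rose. Of 23 cytochrome P450 and other phase I enzymes, 21 rose and none fell, among them the ethanol-oxidising CYP2E1 (8.85). Of 17 phase II conjugation enzymes, 11 rose and 2 fell, with the glucuronosyltransferases UGT2B4 (7.76) and UGT2B10 (6.89), a family whose members share sequence, among the rises. Of 15 hepatic transporters, 11 rose and 1 fell, among them the bile acid importer SLC10A1 (6.11) and SLCO2B1 (6.04). Of 15 genes of bile acid synthesis and its regulation, 12 rose and none fell (13 rose when adjusted over the list alone), including CYP8B1 (6.57), SLC27A5 (4.94) and the bile acid receptor NR1H4 (4.64). The camera adjusted p values with a preset correlation were 1.63e-09, 0.000632, 0.000866 and 9.76e-05. All 4 had adjusted p = 0.499 with an estimated correlation.

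Intermediary metabolism showed rises in most members of its lists. Of 22 genes of the urea cycle and amino acid catabolism, 14 rose and 2 fell, including tyrosine aminotransferase (TAT, 5.82) and serine dehydratase (SDS, 5.11). Of 12 genes of gluconeogenesis and glycogen, 11 rose and 1 fell, among them PCK1 (6.26) and the glucokinase regulator GCKR (3.65). Of 25 genes of fatty acid oxidation and ketogenesis, 16 rose and 1 fell, including the acyl-CoA synthetase ACSL1 (1.91). Of 22 liver transcription factors and nuclear receptors, 17 rose and 2 fell, among them PROX1 (3.99), NR5A2 (2.30) and HNF4A (0.88, SE 0.20, edgeR adjusted p = 0.00472). With a preset correlation camera gave adjusted p values of 0.000998, 0.000371, 0.000632 and 0.000699. The calls were lost with adjusted p = 0.499 with an estimated correlation, and adjusted p = 0.564 with an estimated correlation for fatty acid oxidation.

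Lipid and sugar pathways outside these moved in both directions. Of 25 cholesterol synthesis genes, 5 rose, such as TM7SF2 (2.59), and 10 fell, such as FDPS (-1.27) and ACAT2 (-1.19), with a camera adjusted p of 0.229. Of 26 genes of lipogenesis and the lipid droplet, 13 rose and 6 fell (14 and 7 adjusted over the list alone; camera adjusted p = 0.133), with rises of the droplet coat gene PLIN1 (5.31), the lipoprotein assembly gene MTTP (4.53) and MLXIPL (3.22). Of 22 genes of glycolysis and hypoxia, 6 rose, such as NDRG1 (3.24), and 8 fell, such as PFKP (-3.32), CA9 (-2.24) and SLC16A3 (-1.38), with a camera adjusted p of 0.365.

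Cell division genes fell without exception. All 27 DNA replication genes fell, including CDC45 (-2.81), MCM10 (-2.73) and TK1 (-2.62), and all 29 mitosis genes fell, including CENPE (-2.86), CCNB1 (-2.68) and PLK1 (-2.62). Of 27 mesenchymal and extracellular matrix genes, 24 fell and 1 rose, with falls of POSTN, TAGLN, LUM and VIM (-0.99). Of 17 targets of TGF-beta and YAP signalling, 10 fell and 3 rose, including ITGB6 (-3.78), THBS1 (-3.52) and TGFB2 (-2.88). Of 13 fetal liver and progenitor genes, 10 fell, including H19 (-1.83), IGF2BP3 (-1.75), SOX4 (-1.71) and alpha-fetoprotein (AFP, -1.27), and PEG10 rose (1.70). Of 20 targets of p53, 11 fell and 1 rose, including GDF15 (-2.33), FDXR (-1.47) and BAX (-1.26). Camera adjusted p values with a preset correlation were 6.09e-11, 1.47e-11, 6.20e-10, 0.00684, 0.00145 and 0.00316 in the order given. All 6 had adjusted p = 0.499 with an estimated correlation.

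Markers of other liver cell types showed no common direction. Of 13 cholangiocyte markers, 5 rose, such as DEFB1 (2.64), SPP1 (2.59) and SOX9 (2.36), and 6 fell, such as CD24 (-3.24), KRT7 (-1.85) and KRT19 (-0.82). This list had a median of 0.00, a mean of 0.24 and a camera direction of down at an adjusted p of 0.789. The 2 endothelial markers that could be tested rose, KDR by 2.65 and EGFL7 by 0.28, and so did the 2 macrophage and lymphocyte markers, CD14 by 0.81 and CD68 by 0.34. KDR is a receptor for vascular growth factor and CD68 a lysosomal protein, and neither of the lists had enough members for camera.

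Apart from the p53 and the TGF-beta and YAP targets above, stress and signalling lists were mixed, except for metallothioneins and mitochondrial transcripts. Of 5 metallothioneins, which bind metals and are close paralogs, 4 rose, including MT1X (3.85), MT1F (2.90) and MT2A (1.84). Of 13 mitochondrially encoded mRNAs, 12 rose, including MT-ND4L (2.67) and MT-ND2 (1.94), and the mitochondrial share of UMIs was higher in the same libraries, as given above. The camera adjusted p values of these 2 lists were 0.00985 and 0.000346 with a preset correlation. Both had adjusted p = 0.499 with an estimated correlation. Of 20 immediate early genes, which also respond to cell dissociation, 6 rose and 8 fell, with NR4A1 at 1.995 and FOSB at -3.15 (camera adjusted p = 0.628). Of 23 genes of the unfolded protein and integrated stress response, 7 rose, such as CHAC1 (1.36), and 11 fell (12 adjusted over the list alone), such as PPP1R15A (-1.39), with a camera adjusted p of 0.229. Of 24 interferon response genes, 11 rose, such as IRF7 (3.22), and 6 fell, such as EPSTI1 (-3.67) and OASL (-2.39), with a camera adjusted p of 0.352.

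Among 16 NF-kB and chemokine genes, 5 rose, such as CXCL8 (1.44), and 8 fell (10 adjusted over the list alone), such as BIRC3 (-2.56) and CCL20 (-2.19), with a camera adjusted p of 0.169. Among 14 glucocorticoid targets, 9 rose (10 adjusted over the list alone), such as ERRFI1 (2.51), and 3 fell, such as ANGPTL4 (-2.16), with a camera adjusted p of 0.0995. Among 17 NRF2 targets, 8 rose (9 adjusted over the list alone), such as GPX2 and the sequence-sharing AKR1C2 (2.08), and 4 fell, with a camera adjusted p of 0.169. Among 10 Wnt targets and pericentral genes, 6 rose and 3 fell (camera adjusted p = 0.252); the highest rise was that of CYP2E1, a hepatocyte P450, and RNF43 rose by 1.75 while TCF7 fell by 1.21. Among 33 ribosomal protein genes, 6 fell (4 adjusted over the list alone), such as RPS2 (-1.23), and none rose, with a camera adjusted p of 0.0933. For every list of this comparison without a second count here, the counts were the same when adjusted over the list alone.

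**Figure D2:**
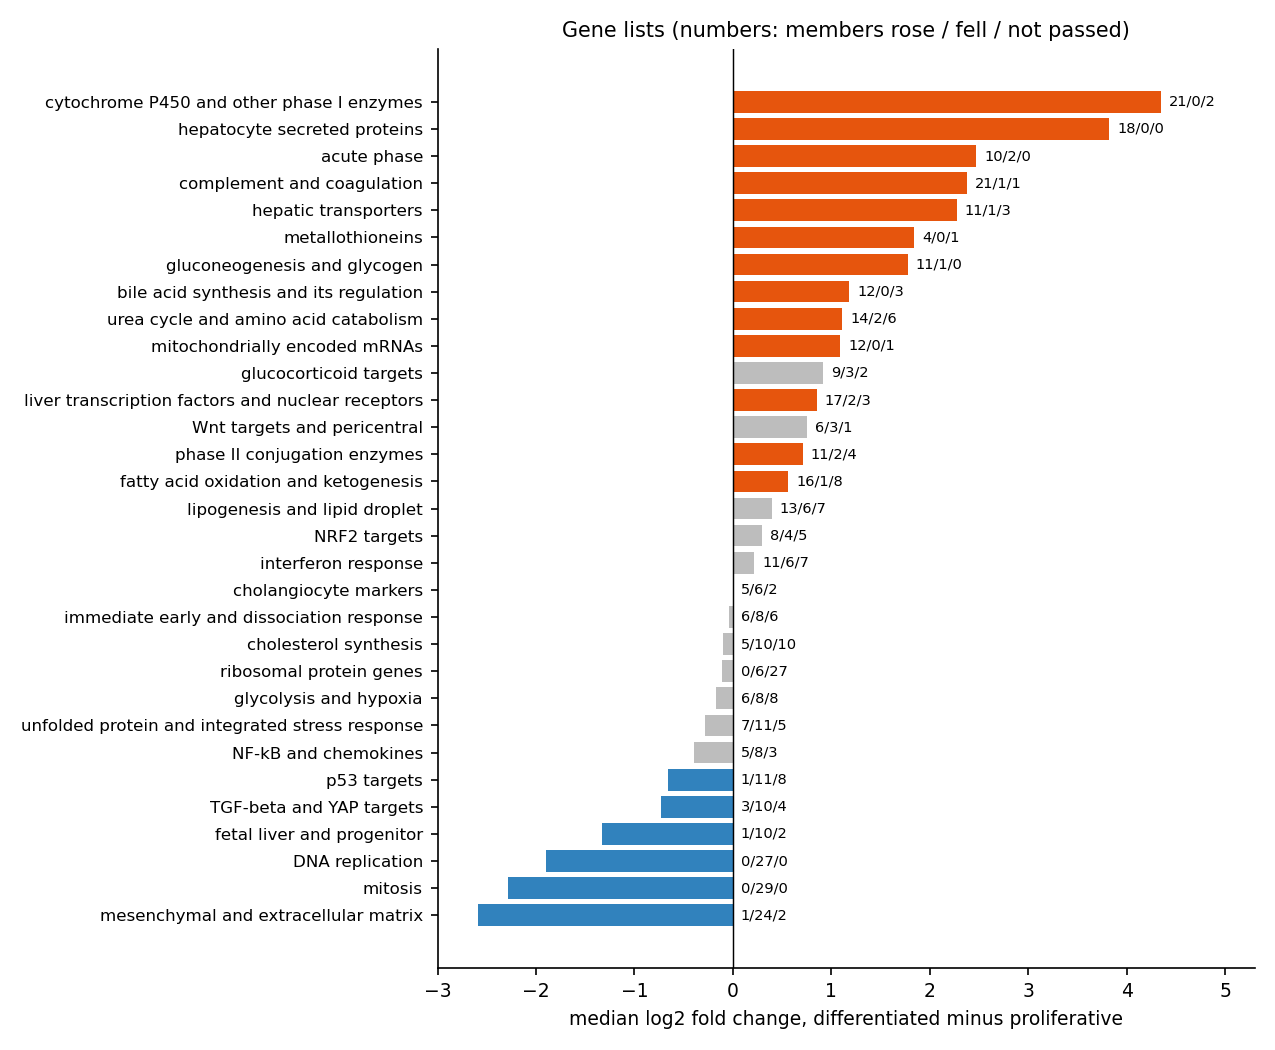
Median log2 fold change on differentiation of each gene list with at least 5 tested members, coloured where the camera adjusted p with a preset correlation was under 0.05; the numbers beside the bars are the members that rose, fell and did not pass. Mitosis (29 fell of 29) and phase I enzymes (21 rose of 23) have medians of -2.28 and 4.35, and no median changes when members with 3 counts or fewer in each library of a treatment are set at that bound.

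Across all genes, 9369 of 13944 tested changed at an adjusted p of 0.05 in edgeR's quasi-likelihood test with the line as a covariate, 4899 up and 4470 down. The fold changes of the lines at day 28 were closely related across 6247 genes with a mean log2 CPM of at least 4 (Pearson's r = 0.961, Spearman's rho = 0.942 across genes, which are not independent replicates), and the slope of dCas9 on WT was 0.81. The p values assume that lines and days stand in for replicates. On simulated data 8.81% of the calls for this comparison were false. That share cannot be carried over to the 9369 genes, since few genes were changed in the simulation and 193 were called. With cells limited to those of at least 1000 genes and at most 10% mitochondrial UMIs, the fall of MKI67 was no longer past the threshold.

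The comparison of the dCas9 line with the WT line asked how far carrying dCas9-KRAB goes with a different transcriptome. ZNF10, the zinc finger gene from which the KRAB domain used in such repressors is taken, was higher by 4.599 (log2, SE 0.23, edgeR adjusted p = 0.000582) in the dCas9 libraries, with 109 and 86.6 CPM against 2.87, 5.34 and 5.38 CPM in WT day 5, day 28 and day 42. PAGE5, a cancer and testis antigen gene chosen after its values were seen, differed by -3.08 (SE 0.23, edgeR adjusted p = 0.00526), with 0.782 and 0.860 CPM against 4.92, 10.8 and 8.64 CPM. These were the only 2 genes past the threshold among 13944 tested. A difference between the lines at day 5 alone counts as spread in this additive fit, so it could hardly pass. Of 5626 genes at 20 CPM or more in either library, 52 differed by at least 2-fold between dCas9 and WT at day 5. At day 28 it was 7 of 5245 genes. ZNF10 (ENSG00000256223) lies on chromosome 12 at 133130575 to 133159465 on the plus strand, and PAGE5 lies on chromosome X at 55220355 to 55224108. With cells thinned to 20000 UMIs, a ZNF10 UMI was found in 76.0% and 67.9% of the dCas9 day 5 and day 28 cells, and in 5.70%, 10.2% and 10.5% of the WT day 5, day 28 and day 42 cells, which lack the construct. Median depths before thinning were 37090.5 and 27799 UMIs in those dCas9 libraries and 39427, 30014 and 34530.5 UMIs in the WT libraries; without thinning the shares were 88.3%, 78.8%, 11.3%, 15.3% and 18.3%.

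Hepatocyte lists leaned up and cell division lists leaned down in the dCas9 line, with no member past the threshold over all genes. The mitosis list had a median of -0.39 with 0 of 29 members past the threshold, for example PLK1 at -0.65 and CCNB1 at -0.62, and DNA replication a median of -0.28 with 0 of 27, for example TK1 at -0.42. Complement and coagulation had a median of 0.51 (0 of 23 past the threshold; F12 at 1.03), acute phase 0.66 (0 of 12; HP at 0.94) and hepatocyte secreted proteins 0.49 (0 of 18; FGG at 0.91), of which 4 secreted protein genes passed as higher when adjusted over the list alone. The phase I list had a median of 0.33 (0 of 23 past the threshold), with 4 higher and 1 lower adjusted over the list alone. Camera with a preset correlation gave adjusted p values of 1.68e-16 (mitosis), 3.66e-09 (DNA replication), 1.49e-11 (complement), 2.44e-05 (acute phase), 2.55e-07 (secreted proteins) and 1.29e-06 (phase I). These calls were lost with adjusted p = 0.566 with an estimated correlation for each of the 6.

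The preset correlation called 19 of 31 lists, 17 up and 2 down. None held with an estimated correlation, which called no list in any comparison and so cannot decide. Lists of other functions were called up too, namely ribosomal protein genes (adjusted p = 2.46e-06), immediate early and dissociation genes (8.68e-05) and mitochondrially encoded mRNAs (0.000118), each with adjusted p = 0.566 with an estimated correlation. The lean of cell division lists goes with the day 5 libraries, in which cycling-like cells were 58.0% (WT) and 31.6% (dCas9), against 5.66% and 6.66% at day 28 (10.2% and 9.68% with the differentiated libraries clustered alone). Other lists called up included urea cycle genes (3 higher adjusted over the list alone; GNMT at 0.70), gluconeogenesis (2 higher adjusted over the list alone), bile acid genes (1 higher adjusted over the list alone; AKR1C4 at 1.15) and NF-kB and chemokine genes (4 higher adjusted over the list alone; CXCL8 at 0.87, SOCS3 at 0.67). Their adjusted p values were 8.52e-06, 0.000118, 0.000783 and 0.00104. The corresponding values were adjusted p = 0.566 with an estimated correlation, and adjusted p = 0.569 with an estimated correlation for NF-kB. Adjusted over the list alone, 1 mesenchymal gene was higher (DCN, 0.94) and 1 lower, EGFL7 (-0.44) was lower, and CD14 (0.52) and CYP2E1 (1.15) were higher. ALB (0.34), CYP3A4 (0.33), MKI67 (-0.39) and HNF4A (0.04) did not pass.

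At an unadjusted p of 0.05, 706 genes passed, against 697.2 by chance, in a fit that counts differences at day 5 alone as spread. DESeq2 called 36 genes. The count was 41 without WT day 5, 42 without dCas9 day 5, 758 without dCas9 day 28 and 4 without WT day 42. In a fit without treatment as a covariate it was 0 with edgeR, where 7 genes passed unadjusted; the value of ZNF10, dCas9 against WT libraries, was then 4.47, and that of PAGE5, dCas9 against WT libraries, -3.26.

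The size of the differentiation change was then compared between the lines by testing the interaction of line and treatment. Some hepatocyte and acute phase genes that were higher in the dCas9 day 5 library rose less in that line, while most members of the hepatocyte lists did not pass. SULT2A1, a sulfotransferase of steroids and bile acids, differed by -3.55 (log2, SE 0.34, edgeR adjusted p = 1.21e-11), with 0.0739 and 0.882 CPM in WT and dCas9 day 5 against 77.7 and 80.9 CPM at day 28. MGP, an inhibitor of matrix calcification, differed by -2.71 (SE 0.24, edgeR adjusted p = 7.33e-13), with 2.15 and 10.9 CPM at day 5 and 26.6 and 21.0 CPM at day 28. Among genes with a mean log2 CPM of 4 or more, FABP1 (-3.06), ADH1B (-2.52) and SAA2 (-2.08) were the next in this direction. The difference of FABP1 rests on a few cells, since without the 32 dCas9 and 6 WT day 5 cells in clusters of mostly differentiated cells FABP1 differed by -0.09 (SE 0.67, edgeR adjusted p = 0.999). At the same minimum, the genes that differed most the other way were GAGE12F (1.29), SCG5 (1.12), TF (1.07), MAT1A (1.01) and HYI (0.94); GAGE12F belongs to a family of near-identical genes and its count is uncertain.

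Of the lists, acute phase had 6 of 12 members with a smaller change in dCas9 and none with a larger one (9 smaller and 2 larger adjusted over the list alone), among them SAA4 at -2.02 and the endotoxin-binding LBP at -1.72. Phase I enzymes had 4 of 23 smaller (9 adjusted over the list alone), complement and coagulation 3 of 23 smaller (10 smaller and 2 larger adjusted over the list alone), with CPB2 at -1.46 and C6 at -1.39, and fatty acid oxidation 2 of 25 smaller, among them ACSL1 at -0.93. Camera with a preset correlation gave adjusted p values of 8.40e-08, 0.000137, 0.00178 and 3.60e-05. These were lost with adjusted p = 0.757 with an estimated correlation. The secreted protein list went both ways, with HPX at 2.07, FGG at -1.78 and FGA at -1.29. DNA replication genes had a median of 0.42 with no member past the threshold, for example TK1 at 0.56 (camera adjusted p = 2.84e-07; adjusted p = 0.757 with an estimated correlation).

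In all, 197 of 13944 genes passed, 177 with a smaller or more negative change in the dCas9 line and 20 with a larger one. The 20 became 50 with thinned cells, 5 with DESeq2, and 0 in edgeR with RLE or with cells of at least 1000 genes and at most 10% mitochondrial UMIs, so that direction is the less certain. All 177 were higher in dCas9 than in WT at day 5 (median 1.31 log2), with a median difference of 0.02 at day 28, and 147 of them rose on differentiation. With no choice by this test, 3959 of the 4895 genes that rose on differentiation (genes that mark sex left out) were higher in dCas9 at day 5, with a median interaction of -0.17, and the 4466 genes that fell had a median interaction of 0.18. The test has 1 residual degree of freedom, from WT day 28 and day 42, and on simulated data 25% of its calls were false. The count was 10 with RLE size factors, 101 with DESeq2, 119 with filterByExpr, 2 with cells of at least 1000 genes and at most 10% mitochondrial UMIs, and 0 with edgeR and no low-count filter, where 1010 genes passed at an unadjusted p of 0.05; the median change and SE of the 197 genes were -1.23 and 0.28 with TMM and -1.24 and 0.30 with RLE, while the prior degrees of freedom that edgeR estimates for the spread were 62.1 and 8.14. With that number set to 62.1 in each fit, 265 genes passed with RLE, 411 with no low-count filter and 172 with the limits on cells.

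**Figure D3:**
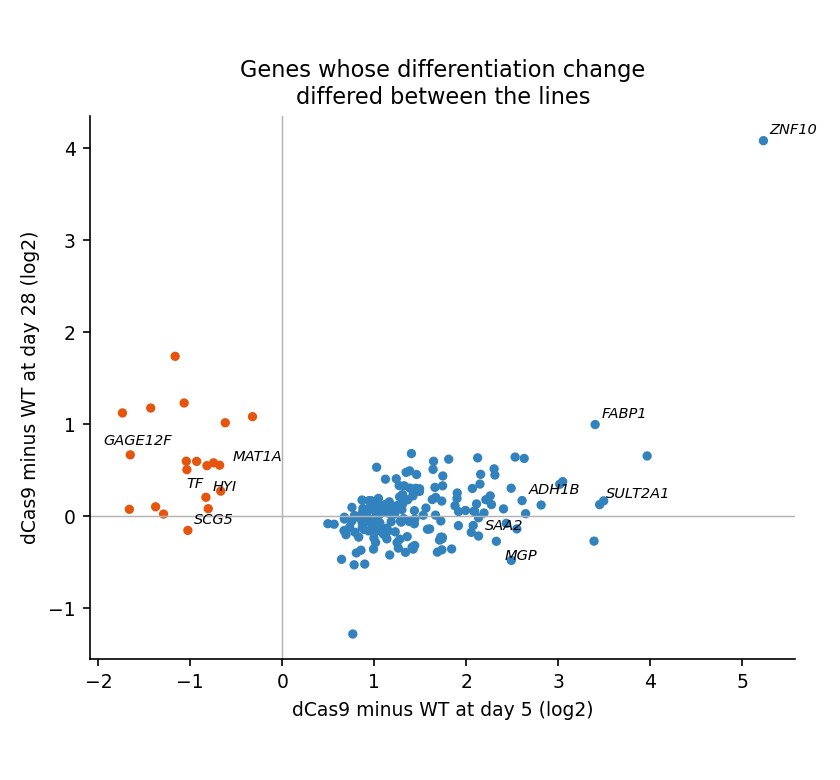
Difference between dCas9 and WT at day 28 (log2, vertical axis) against the same difference at day 5 (horizontal axis) for the 197 genes whose change on differentiation differed between the lines, with the named genes and ZNF10 labelled; blue points had a smaller or more negative change in dCas9 and orange points a larger one. The 177 blue points lie to the right of 0 on the horizontal axis, with a median of 1.31, while their median on the vertical axis is 0.02.

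WT day 42 was compared with WT day 28 because the later day was captured, per the series description, to see whether cells can be kept in the differentiated state. With 1 library each there was no test. Of 5488 genes at 20 CPM or more in either library, 82.8% lay within 0.25 log2 of equality, and 1 differed by at least 2-fold, both with 1 CPM added. This gene was EDN1, which encodes the vasoconstrictor peptide endothelin, with 10.2 CPM at day 28 and 21.7 CPM at day 42 (log2 ratio 1.03 with 1 CPM added; counting interval of the ratio without it 1.03 to 1.16). Between WT day 28 and WT day 5, 1395 of 6063 genes differed by at least 2-fold. In whole libraries hepatocyte genes were somewhat higher at day 42, with log2 ratios of 0.50 for ALB and 0.41 for CYP3A4. Within hepatocyte-like cells, described below, they were lower at day 42, with 23382 and 17352 CPM of ALB and 1081 and 761 CPM of CYP3A4 at day 28 and day 42, while these cells were 17.4% and 34.9% of the libraries (10.6% and 16.2% with thinned cells). The class joins clusters 3 and 6, with 13891 and 31031 CPM of ALB and 454 and 1623 CPM of CYP3A4 over all libraries, and cluster 3 was a larger part of it at day 42 (1910 and 686 cells) than at day 28 (1085 and 569 cells).

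The other genes with the highest ratios were the epithelial transcription factor ELF3 (0.95, or a fold of 2.002 with no CPM added), JUN (0.91), the acute phase gene ORM1 (0.87), IL32 (0.86), SLC37A4 (0.85), ERBB3 (0.85), the complement factor CFB (0.85), AMBP (0.83) and MT-ND6 (0.82). The lowest were SPANXC (-0.90), SAA1 (-0.85, from 10519.5 to 5837 CPM), IGFL2-AS1 (-0.82), GATD3B (-0.73), GAGE1 (-0.66), the calcium-binding S100A8 (-0.63), SRGN (-0.60), CSTA (-0.58), MT-ND4L (-0.57) and CDA (-0.56). SPANXC, SAA1, GATD3B and GAGE1 have near-identical paralogs, which leaves their counts uncertain.

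Lists were placed among 10000 random lists of the same size and expression. Random lists hold genes drawn independently, while members of a list may move together, and each day is 1 library. The percentiles therefore describe and do not test. Secreted proteins had a median log2 ratio of 0.52 with 14 of 14 members higher at day 42, complement and coagulation 0.49 with 10 of 11 higher, and phase I enzymes 0.33 with 11 of 11 higher, each above all the random lists. Mitosis genes had a median of 0.52 with 13 of 13 higher, also above all the random lists, with MKI67 at 0.51, and DNA replication genes 0.27 with 8 of 8 higher (99.9th percentile). Lists of other functions were also high, with medians of 0.20 for immediate early and dissociation genes (17 of 17 higher, 99.97th percentile), 0.27 for mitochondrially encoded mRNAs (9 of 13, 99.975th), 0.41 for fetal liver genes (5 of 5, 99.9th), 0.21 for cholangiocyte markers (7 of 7, 98.9th) and 0.15 for mesenchymal genes (8 of 10, 98.3th). The p53 targets had a median of -0.09 with 13 of 17 lower (1.80th percentile). The median for all 5488 genes was 0.03. The count of genes at 2-fold was 36 when cells were limited to at least 1000 genes and at most 10% mitochondrial UMIs, 4 with a minimum of 5 CPM, 2 with thinned cells, and 0 with a pseudocount of 5 CPM, with TMM-scaled CPM or with a minimum of 100 CPM.

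**Figure D4:**
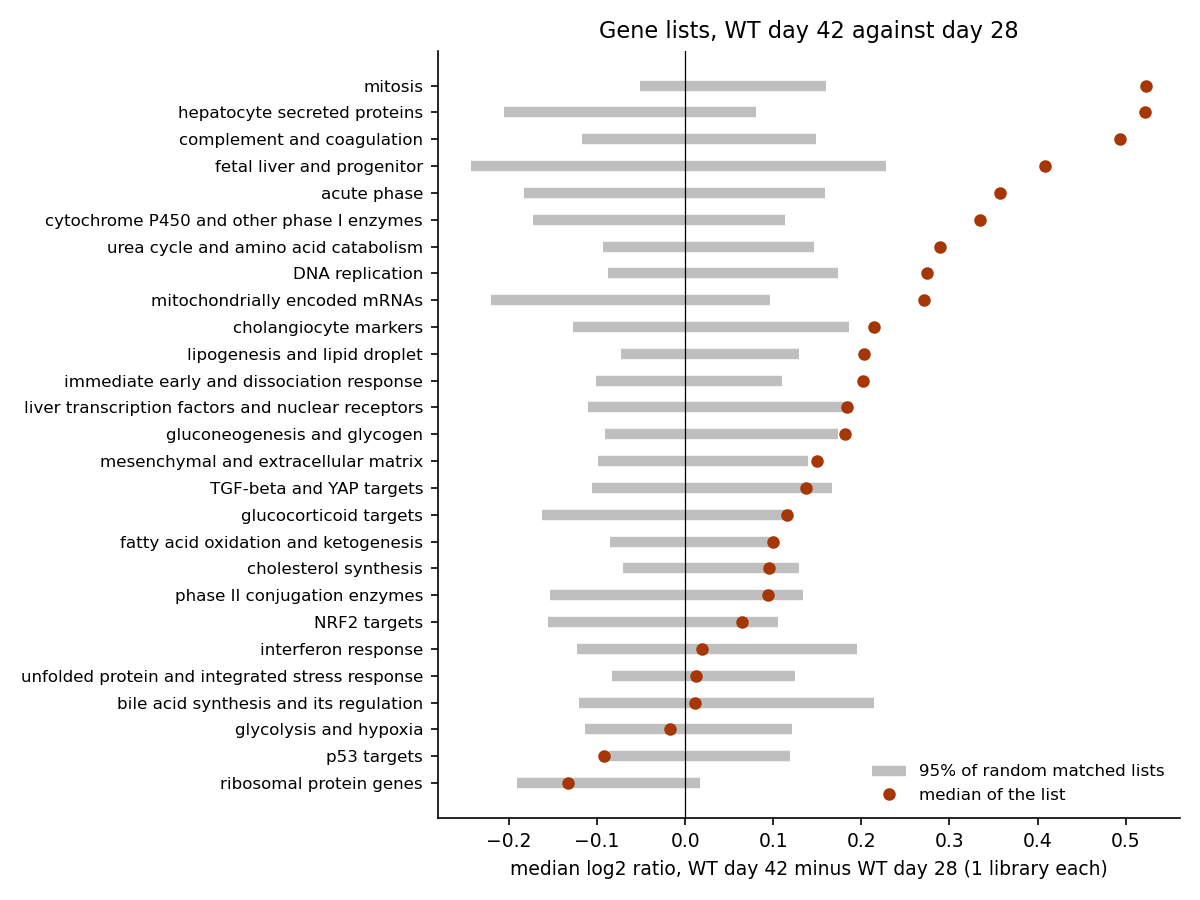
Median log2 ratio of WT day 42 to WT day 28 for each gene list (points), 1 library each, with grey bars for the central 95% of medians of random lists matched on size and expression. Mitosis and hepatocyte secreted proteins have the highest medians, 0.52 each, and lie outside their grey bars.

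Single cells of the 5 libraries fell into 11 clusters, which were named only where markers fixed beforehand stood out. Day 5 cells fell into a mesenchymal-like class (cluster 1, with POSTN, LUM and DCN) and a cycling-like class (clusters 4 and 5, with MKI67 and TOP2A). Cluster 1 had the highest COL1A1 (21.0 CPM) of the clusters, but also the highest KRT19 (1177 CPM). VIM stood there at 5.86 CPM, below cluster 8 (12.6 CPM), so the name rests on matrix genes. Cycling-like cells were 58.0% of WT day 5 and 31.6% of dCas9 day 5 cells, and 5.66%, 6.66% and 8.37% of WT day 28, dCas9 day 28 and WT day 42 cells (cluster 7), or 10.2%, 9.68% and 13.4% when the differentiated libraries were clustered alone. Hepatocyte-like cells (clusters 3 and 6, with ALB, CYP3A4, TF and FGB) were 17.4% (16.7 to 18.2) of WT day 28, 23.2% (22.4 to 23.9) of dCas9 day 28 and 34.9% (33.9 to 36.0) of WT day 42 cells. Cluster 3 held 11.4%, 13.1% and 25.7% of these libraries, and cluster 6, with more of the hepatocyte markers, 5.996%, 10.1% and 9.23%. Most other differentiated cells, 76.9%, 70.2% and 56.7%, were in clusters with no name. The largest of these was cluster 0, led by genes such as SAA1, PDK4 and HSD11B2, and next came cluster 2, led by the chemokine CXCL13, KDR, PDPN and CHI3L1. Over all libraries ALB stood at 147 and 134 CPM in clusters 0 and 2, against 489, 352 and 364 CPM in day 5 clusters 1, 4 and 5. HNF4A stood at 1.77 and 1.40 CPM against 8.77, 5.55 and 10.2 CPM. CYP3A4 went the other way, at 8.13 and 20.6 CPM against 0.368, 0.0808 and 0.0766 CPM. So did TTR, at 7.02 and 8.20 CPM against 2.56, 3.01 and 4.05 CPM. No cluster was named cholangiocyte-like: in WT day 28, KRT19, a keratin of bile duct cells, stood at 505 CPM in hepatocyte-like and 519.7 CPM in unnamed cells, SOX9 at 19.3 and 21.8 CPM, and KRT7 at 1.46 and 5.04 CPM. Over all libraries KRT19 stood at 333 CPM in cluster 6 and 726 CPM in cluster 3, and SPP1 was highest in cluster 2, at 22.4 CPM.

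**Figure D5:**
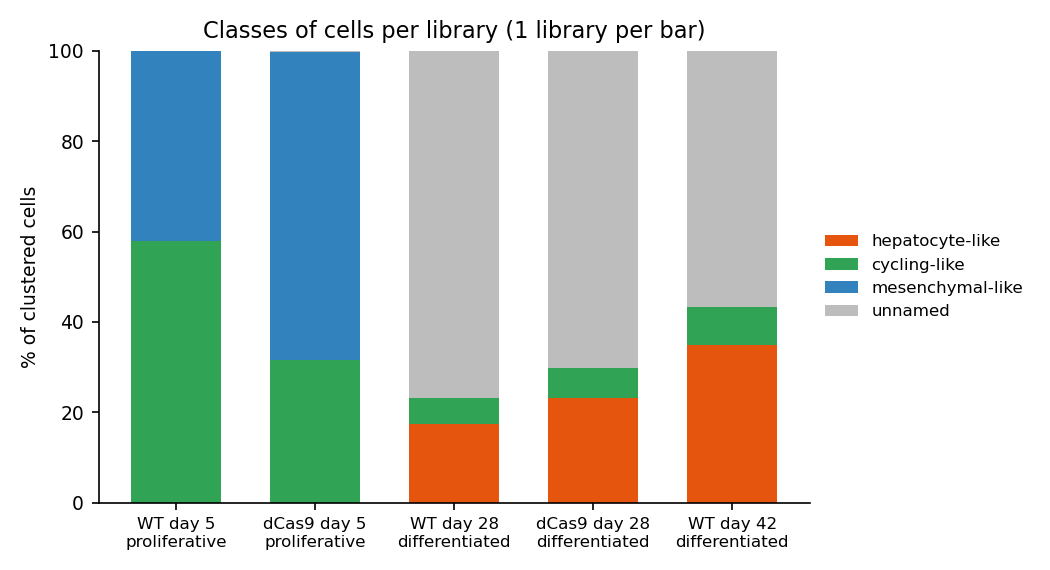
Percent of clustered cells in each named class and in unnamed clusters, 1 bar per library; shares are of 1 library each. Hepatocyte-like cells are found in the 3 differentiated libraries, at 17.4%, 23.2% and 34.9%, and mesenchymal-like cells in the 2 proliferative libraries, at 41.9% and 68.1%.

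A CYP3A4 UMI was found in 68.3%, 66.0% and 58.8% of the hepatocyte-like cells of WT day 28, dCas9 day 28 and WT day 42 after thinning to 20000 UMIs. In the unnamed cells of the same libraries the shares were 10.2%, 11.4% and 14.7%, and in day 5 cells 0.206% (WT) and 0.474% (dCas9). The day 5 libraries held almost no CYP3A4 RNA, so their shares do not measure free RNA in the differentiated libraries, and a CYP3A4 UMI in an unnamed cell is not read as expression. Median depths before thinning were 37734, 34678 and 39677 UMIs in hepatocyte-like cells, 28383.5, 25645 and 31082.5 UMIs in unnamed cells, and 39427 and 37090.5 UMIs in the WT and dCas9 day 5 cells. Without thinning the hepatocyte-like shares were 72.6%, 69.4% and 66.3%. A MKI67 UMI was found in 56.3% and 32.0% of WT and dCas9 day 5 cells, and in 7.20%, 8.35% and 10.7% of WT day 28, dCas9 day 28 and WT day 42 cells, against 1.57%, 1.94% and 2.48% of the hepatocyte-like cells. Without thinning these MKI67 shares were 60.9%, 33.8%, 7.74%, 8.26% and 11.9%.

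Hepatocyte-like cells were also compared with the unnamed differentiated cells, whose cluster 8 also carries cycling genes (MKI67 at 94.98 CPM against 321 CPM in cluster 7), on genes at 20 CPM or more that had not been used for clustering. Of 4921 such genes, 88 were higher and 88 lower by at least 2-fold in all 3 libraries (113 and 199 at double the clustering resolution). DDC, an amino acid decarboxylase, had log2 ratios of 4.04, 3.90 and 4.03 in WT day 28, dCas9 day 28 and WT day 42, coagulation factor V (F5) 3.24, 3.11 and 3.40, and the growth factor receptor FGFR4 2.69, 2.81 and 2.68. Among the lowest were GGT5 (-2.86, -2.26 and -2.57), the laminin gene LAMB1 (-1.91, -1.76 and -1.77) and ANXA1 (-1.92, -1.95 and -1.39). By sign alone, with no minimum fold, 13 of 18 fatty acid oxidation genes and 5 of 5 phase I enzymes were higher in all 3 libraries, against 20.9% of all 4921 genes. Of the other hepatocyte lists, 4 of 6 urea cycle genes and 4 of 7 liver transcription factors were higher, with 2 lower in each. Bile acid genes had 3 higher and 3 lower of 6, and phase II enzymes 1 and 3 of 6. Complement and coagulation had 2 higher and 4 lower of 7, gluconeogenesis 1 and 4 of 6, and lipogenesis 1 and 6 of 9. Of all genes, 67.6% were lower by sign. Members used for clustering were left out, so the few that remain cannot show whether a whole list differs. Of 33 ribosomal protein genes 31 were lower by sign (medians -0.30, -0.30 and -0.19), against 67.6% of all genes (medians -0.21, -0.22 and -0.16). The shares of hepatocyte-like cells depend on the settings of the clustering, and with thinned cells they were 10.6% (WT day 28), 13.7% (dCas9 day 28) and 16.2% (WT day 42). WT day 28 had the lowest and WT day 42 the highest share in each clustering named by the rule used here, but with the naming rule tried first and called doublets kept, dCas9 day 28 (8.92%) lay above WT day 42 (8.32%).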

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

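Among the tests in this part, those of cells from differentiated clusters, of scaling factors, of the prior degrees of freedom, of an introduced ZNF10 sequence and of both explanations for the mitochondrial share were chosen only after the result was seen, and those of cycling cells and of a chromosome 12 gain before.

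A difference between the lines in their change on differentiation stood out in 197 genes in edgeR's interaction test, 177 of them with a smaller or more negative change in the dCas9 line and higher values in the dCas9 day 5 library. The tables argue against a small number of differentiated cells among day 5 cells as the cause, since 189 genes passed without the 32 of 8637 dCas9 and 6 of 7154 WT day 5 cells in such clusters, 187 of them among the 197, but 10 genes lost their call and FABP1 went from -3.06 (SE 0.53) to -0.09 (SE 0.67), which those cells therefore carry. They argue against a lower share of cycling cells, since within the mesenchymal-like cluster the median dCas9 minus WT difference at day 5 was 0.77 with 1 CPM added, against 0.87 for whole libraries, and 176 of 177 genes were higher. The RLE run cannot decide on scaling, since it moved the median of all genes only from 0.0068 to 0.0029. It gave a median of -1.29 for the 177 genes against -1.28 with TMM. A scaling factor shifts all genes of a library alike, and the TMM factors lay between 0.941 and 1.04. Factors of that size are too small to give a median of -1.28 by themselves. But the 177 genes were picked for a negative interaction, and scaling holds the median of all genes (0.0068) near 0. Those 2 medians therefore cannot decide whether an error of scaling remains. The fall to 10 genes with RLE goes with edgeR's prior degrees of freedom, 62.1 with TMM and 8.14 with RLE. At 62.1, 265 genes passed with RLE, and at 8.14, 2 passed with TMM. A different mix of mesenchymal-like states stays open, since at double resolution 1 cluster led by EPYC and DCN held 1266 WT and 4497 dCas9 day 5 cells, as does a difference of the line itself, of culture density or timing, or of the single day 5 libraries.

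ZNF10 was higher in both dCas9 libraries. A gain of its region of chromosome 12 is argued against by the 16 other tested genes within 1 Mb, with a median difference of -0.0644 (range -0.25 to 0.22). ZNF10 UMIs were found in at least 67.9% of thinned cells of a dCas9 library and at most 10.5% of those of a WT library. The KRAB domain of the construct may come from ZNF10, and reads from such an introduced sequence and transcription of the cells' own copy cannot be told apart here, because both would give UMIs in most dCas9 cells.

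The mitochondrial share of UMIs was higher in each differentiated library than in either proliferative library. Depth per cell is argued against as the cause: among cells of 20000 to 40000 UMIs the smallest difference of medians was 4.25 percentage points, against 4.32 among all kept cells. A single kind of differentiated cell is argued against too, since the lowest cluster median among differentiated cells was 9.76% and the highest among day 5 cells 6.57%. A higher mitochondrial content after differentiation, and damage in harvest that differs between the cultures, stay open as untested.

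The genes named for the difference between the lines had these differences in log2 change (dCas9 minus WT), each past the threshold of the interaction test with all cells; that of FABP1 did not pass without a few day 5 cells, as given above. The change, not the level, was smaller in the dCas9 line for SULT2A1 at -3.55, FABP1 at -3.06, MGP at -2.71, ADH1B at -2.52 and SAA2 at -2.08. The change was larger or less negative in that line for GAGE12F at 1.29, SCG5 at 1.12, TF at 1.07, MAT1A at 1.01 and HYI at 0.94.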

How the results depend on the processing

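Leaving out the cells with the highest doublet scores, leaving out day 5 cells in differentiated clusters, both runs with the naming rule tried first, and the runs with set prior degrees of freedom were chosen only after the results were seen.

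No paired analysis was possible because each line and day has 1 library, so no group holds replicate numbers to pair; the line term of the fit compares treatments within each line. The 9369 genes of differentiation stayed within 1.5 times under every alternative run, and leaving out 1 library gave 6369 (without WT day 5) to 8883; of the values of its named genes under alternatives, 499 kept their call and MKI67 lost it at -0.80 with cells of at least 1000 genes and at most 10% mitochondrial UMIs. For the dCas9 line against WT, the 2 genes became 36 with DESeq2, 4 with filterByExpr, 4 with days 5 and 28 alone, 0 with edgeR without treatment as a term (7 unadjusted), 41 without WT day 5, 42 without dCas9 day 5, 758 without dCas9 day 28 (where CYP3A4 at 1.13 and SLC10A1 at 1.64 also passed) and 4 without WT day 42. For the difference between the lines, 197 became 10 with RLE, 101 with DESeq2, 0 with edgeR and no filter (1010 unadjusted), 119 with filterByExpr and 2 with cells of at least 1000 genes and at most 10% mitochondrial UMIs, which leaves 1451 cells in dCas9 day 28 and 1281 in WT day 42. Over these genes the median change and SE were -1.23 and 0.28 before, -1.24 and 0.30 with RLE, -1.25 and 0.29 with no filter and -1.30 and 0.35 with the limits on cells, and edgeR's prior degrees of freedom for the spread were 62.1, 8.14, 3.40 and 9.47, and with 62.1 set in each fit the counts were 265, 411 and 172, while the fit of 197 gave 2, 0 and 13 with theirs, so these calls ended through that number. Among its named genes, with those always included, 163 values kept their status and 46 lost their call in the same direction. Kept status covers genes that did not pass in the main fit, such as ALB and MKI67, so 163 is not a count of calls kept. List calls were 0 with an estimated correlation in both main contrasts, and 19 to 22 and 15 to 21 with 1 library left out. The WT day 42 count of 1 became 0 with a pseudocount of 5 CPM, TMM or a minimum of 100 CPM, 2 with thinned cells, 4 at 5 CPM and 36 with the limits on cells. The 11 clusters became 19 at double resolution. Hepatocyte-like shares in WT day 28, dCas9 day 28 and WT day 42 were 12.02%, 14.2% and 17.2% at double resolution, 12.3%, 17.0% and 21.2% with the differentiated libraries alone, 10.6%, 13.7% and 16.2% with thinned cells, 11.5%, 12.9% and 16.4% without the highest doublet scores, and 5.58%, 8.92% and 8.32% with the first naming rule and called doublets; WT day 42 was 33.2% at a resolution of 0.25. Cycling-like shares in the same libraries were 10.2%, 9.68% and 13.4% with the differentiated libraries alone, where the order of the lines at day 28 reversed, and 8.93%, 9.18% and 12.03% with thinned cells. MKI67 shares were 60.9%, 33.8% and 11.9% without thinning in WT day 5, dCas9 day 5 and WT day 42, and 48.2%, 27.7%, 6.16%, 6.79% and 9.01% at 10000 UMIs in WT day 5, dCas9 day 5, WT day 28, dCas9 day 28 and WT day 42. Genes lower in hepatocyte-like cells were 199 at double resolution. Apart from that and filters that change the genes or cells entering a count, the cause was not tested. No fold change of a named gene reversed its direction, but the hepatocyte-like order of dCas9 day 28 and WT day 42 did with the first naming rule and called doublets, as given, and the differentiation genes were 4616 up and 4721 down with RLE and 4673 and 4754 with DESeq2, against 4899 and 4470. Depth limits what can be said of genes near 1 CPM and of the day 5 shares of hepatocyte genes.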

Other observations

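Unnamed clusters of differentiated cells differed in their leading genes. Cluster 0 held 51.2% of WT day 28, 49.0% of dCas9 day 28 and 33.9% of WT day 42 cells and was led by genes such as SAA1, an acute phase apolipoprotein, PDK4, a kinase that restrains pyruvate oxidation, and HSD11B2, which inactivates cortisol. Cluster 2 held 16.7%, 15.5% and 16.5% of the same libraries and was led by the chemokine CXCL13, KDR, PDPN, CHI3L1 and SPP1. In WT day 28 the unnamed cells had 105 CPM of KDR against 17.9 CPM in hepatocyte-like cells, and 12608 CPM of SAA1 against 4742 CPM. Cluster 10, with 2.48%, 0.921% and 2.09% of these libraries, was led by IGFBP1, TRIB3, DDIT3 and CHAC1, genes of the integrated stress response and its targets. Cluster 9 held 2.94% and 2.44% of the day 28 libraries and 0.269% of WT day 42.

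An ALB UMI was found in 43.8%, 71.3% and 80.1% of the unnamed cells of WT day 28, dCas9 day 28 and WT day 42 after thinning, and in 81.5% and 54.2% of WT and dCas9 day 5 cells, against at least 99.8% of hepatocyte-like cells. Median depths before thinning were 28383.5, 25645 and 31082.5 UMIs in the unnamed cells, 39427 and 37090.5 UMIs in the day 5 cells, and between 34678 and 39677 UMIs in hepatocyte-like cells. ALB is the kind of abundant transcript that free RNA carries into other droplets, so a UMI of it in the unnamed cells is not read as expression. In the day 5 libraries, cells in clusters of mostly differentiated cells held 2 of 104534 ALB UMIs (WT) and 5758 of 172689 (dCas9). These counts cover captured cells only and put no bound on free RNA, so how much of the ALB there was free RNA was not tested.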
